A study of Homo sapiens with 11 samples.

How the data were processed

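RNA sequencing was done on 769-P cells, a human clear-cell renal carcinoma line, in 11 libraries: 4 with a control siRNA (siSCR), 3 with a first siRNA against AKR1A1 (si1) and 4 with a second one (si2). Per the labels' protocols, cells grown in 6-well plates were transfected with a lipid reagent for 48 h, with the siRNA labelled at 20 µM. Total RNA was taken with a column kit. Per the submitters' processing notes, reads were trimmed with cutadapt, inspected with FastQC, aligned with STAR to GRCh38, counted per gene with HTSeq and normalized with the relative log expression (RLE) size factors of DESeq2. The versions of these tools, the strandedness of the libraries and the siRNA sequences were not given in the sources used here.

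The authors deposited 1 table per siRNA against the control, each with 33080 genes, of which 17626 had a read in some library. Each library's column in the deposited tables held log2 values, the log2 of the RLE-normalized count plus 1, which was tested on the values: undone, 100% of the values of each library lay within 0.01 read of a whole multiple of 1 step. The whole reads behind the values were recovered in this way, and their sum was taken as the depth of a library. Size factors computed again from the recovered reads lay within 0.0458% of the deposited scale over all 11 libraries, and the control columns were equal in both tables (largest difference 0), so both siRNAs were on one scale. Per the file headers, the authors also deposited the mean normalized signal of a table's libraries, a log2 fold change, a p-value and an adjusted p-value from DESeq2, with settings not given in the sources used here. These were used only where the authors' deposited table is named.

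The comparisons were si1 against siSCR, si2 against siSCR and si2 against si1, each fitted on its own libraries with group as the only term. The lists of genes, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The plan named a count-based test for raw counts and limma for normalized values. Since the deposited unit was log2, limma 3.58.1 in R 4.3.3 was run on log2(normalized count + 1), with empirical Bayes moderation and neither a mean trend nor robust fitting. Genes were kept when their normalized count was at least 10 in as many libraries as the smaller group held. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; all tests were two-sided unless stated. Errors of fold changes are standard errors from limma. Values of single genes are mean normalized counts with their SD over libraries. Group differences in the log2 level of AKR1A1 and in the share of mitochondrial reads were also tested with exact permutation tests, whose p is the smaller tail doubled.

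Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 of 33 lists that had at least 5 tested members, and again with a correlation estimated per list. The lists covered aldo-keto reductases, glucuronate and polyol metabolism, NRF2 targets, ferroptosis, nitric oxide, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glycolysis, HIF targets, oxidative phosphorylation and the tricarboxylic acid cycle. They also covered S phase, mitosis, p53 targets, the ATF4 response, endoplasmic reticulum chaperones, heat shock, interferon-stimulated genes, NF-kB targets, the TGF-beta response and matrix, epithelial junctions, renal lineage, lysosome and autophagy, apoptosis, MYC targets, ribosomal proteins, histones, mitochondrial transcripts, the small RNA pathway, and markers of fibroblasts, leukocytes and endothelium. Of the listed genes, 8 had no match in the tables. Symbols were brought up to date and positions were taken from GENCODE 29 on GRCh38, matched by Ensembl identifier. For each list and library, a list score was computed as the mean log2 level of the members, each centred on its mean over all libraries.

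Named genes followed a fixed rule: AKR1A1, and for each siRNA against siSCR the 8 largest rises and 8 largest falls among called genes that had an official symbol, a mean normalized count of at least 100 in the higher group and every library of one group above every library of the other. For genes called with both siRNAs, the 8 with the largest smaller fold change in each direction were named under the same filters, and for si2 against si1 the 5 highest in each siRNA. For a list, up to 4 called members with the largest fold changes were named, or, with none called, the 2 members of highest level.

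The siRNA comparisons share their controls, so the number of genes called with both siRNAs and the correlation of the fold changes were set beside 100 simulated data sets without any siRNA effect, and beside fits in which each siRNA had 2 controls of its own. The alternatives were upper-quartile rescaling, no filter, a minimum of 50, limma-trend, pseudocounts of 0.5 and 5, all 11 libraries in one fit, the replicate number as a block, a log2 fold change of at least 1 in size, and each library left out in turn. The fits with a block used only replicate numbers present in both groups. Added after seeing the data were limma-voom on the recovered reads, the log2 share of mitochondrially encoded reads as a covariate, and fits without both siSCR 1 and si1 1.

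The sequences of 3′ UTRs were searched for 7-mers, using the transcript with the longest coding sequence of each gene in GENCODE 29. The score of a 7-mer set the fold changes of genes that carry it against those of other genes, after removing linear trends with 3′ UTR length, GC content and mean level, beside 1000 permutations of the genes. AKR1A1 was left out of this search. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures were drawn with matplotlib 3.10.9.

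The limma fit was tested on simulated counts with 4 sizes of change in 50 genes each. These were drawn independently, with 1 dispersion for all genes (0.0278, a median over genes) and no outlying library. The real libraries hold siSCR 1, which stood apart from the other controls, so fewer changes may be called in them. A log2 change of 1 was called for 68%, 76% and 76% of the changed genes in si1 against siSCR, si2 against siSCR and si2 against si1, and a change of 2 for 100% in each. A change of 0.5 was called for 4%, 0% and 6%, so changes of that size or smaller were mostly not detectable even in such data. Of the simulated calls, 7.48%, 6.76% and 9.03% were false. No deposited sample column was left out.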

Results

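Gene-level RNA sequencing was done on 11 libraries of 769-P cells, a human clear-cell renal carcinoma line, 48 h after transfection with an siRNA. The control siRNA (siSCR) had n = 4 libraries, the first siRNA against AKR1A1 (si1) had n = 3 and the second (si2) had n = 4. Reads counted on genes, in replicate order, were 3836109, 2847615, 2271348 and 2965494 for siSCR, 3880155, 2189728 and 2108546 for si1, and 3512868, 3756237, 2958944 and 5939514 for si2. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. The labels describe no molecular identifiers, so intervals of shares cover counting error only.

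The most abundant transcripts on average were MT-CO3, MT-ND4, MT-CO2, GAPDH and RPL27A, with MT-CO3 at 1.22% of the recovered reads of all libraries together. In siSCR 1, mitochondrially encoded transcripts took 12.1% of the reads (95% Wilson interval 12.1% to 12.2%), against 3.46% to 4.46% in the other siSCR libraries. In si1 the share was 8.48% ± 2.32 (SD, n = 3) and in si2 4.89% ± 0.244 (SD, n = 4), and siSCR as a group had 6.09% ± 4.06 (SD, n = 4). The exact permutation p of the share was 0.4 for si1 against siSCR, 1 for si2 against siSCR and 0.0571 for si2 against si1. With the smaller tail doubled, 0.0571 is the smallest p that 35 splits allow. In si1 2, 11606 genes were detected at a common depth of 2108546 reads, against 13086 to 13619 in the other libraries. Correlations of log2 levels between libraries of a group were 0.916 to 0.975 in siSCR, 0.888 to 0.954 in si1 and 0.954 to 0.978 in si2; siSCR 1 reached 0.916 to 0.931 with the other siSCR libraries. The first principal component held 34.6% of the variance, with si1 2 farthest out, and the second held 21.6%.

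AKR1A1, an NADPH-dependent aldehyde reductase that acts on D-glucuronate among other substrates, was lower with both siRNAs than with the control siRNA. Its mean normalized count was 272 ± 82.3 (SD, n = 4) in siSCR, 50.1 ± 29.4 (SD, n = 3) in si1 and 45.8 ± 10.2 (SD, n = 4) in si2. The gene (ENSG00000117448) lies on chromosome 1 of GRCh38 from 45550543 to 45570049. The log2 fold change was -2.54 (SE 0.42; limma adjusted p = 0.0357) for si1 and -2.53 (SE 0.24; limma adjusted p = 0.00218) for si2. Exact permutation tests gave p = 0.0571 for si1 and p = 0.0286 for si2. With the smaller tail doubled, these are the smallest that 35 and 70 splits allow. AKR1A1 did not differ detectably between the siRNAs, with a log2 difference of 0.01 (95% interval -0.89 to 0.92; exact permutation p = 0.971). For si1 the limma adjusted p rose to 0.0871 with no filter on low values, and to between 0.0659 and 0.126 when any library other than siSCR 1 was left out.

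**Figure D1:**
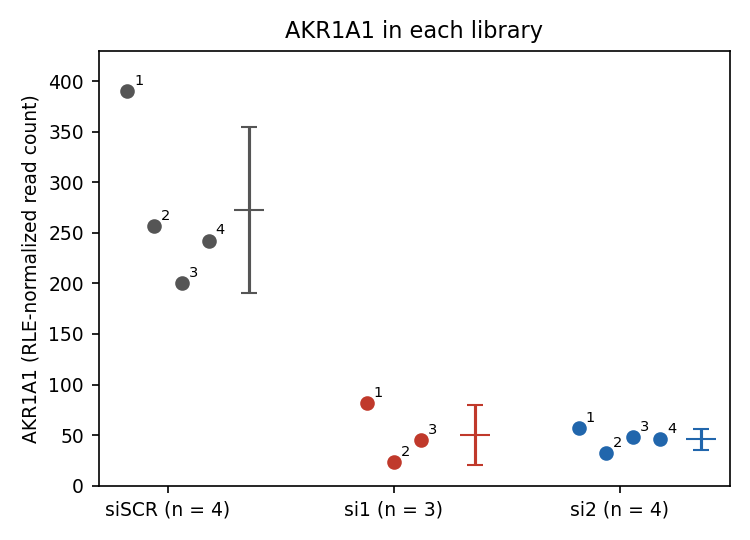
Normalized AKR1A1 count of each library (vertical axis) by siRNA group (horizontal axis), with points numbered by replicate and bars at the mean ± SD. The siSCR libraries sit between 200.1 and 390, and every si1 and si2 library sits between 23.6 and 81.7.

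The comparison of si1 with siSCR asks which transcripts differ 48 h after AKR1A1 is lowered with the first siRNA. Among the largest rises was ABCA12, a lipid transporter, from 39.0 ± 17.7 (n = 4) to 312 ± 125 (n = 3). Another was ANKRD1, a target of the YAP coactivator, from 17.6 ± 6.87 (n = 4) to 107 ± 19.3 (n = 3). BTG2 and PMAIP1, antiproliferative and proapoptotic genes induced by p53, rose by 2.07 and 1.85 on the log2 scale. ERLIN1, an endoplasmic reticulum protein that takes part in the degradation of membrane proteins, fell from 101 ± 30.7 (n = 4) to 5.73 ± 4.58 (n = 3). DEPDC1 and PRR11, genes expressed with the cell cycle, fell by 3.55 and 2.37 on the log2 scale. BECN1, a core autophagy gene, fell by 2.26, and GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, fell by 2.35.

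The limma adjusted p was 0.0318 for ABCA12 (log2 fold change 2.99, SE 0.37), for ANKRD1 (2.63, SE 0.36) and for ERLIN1 (-4.13, SE 0.53), and 0.0185 for BECN1 (SE 0.20). ABCA12 lies on chromosome 2 from 214931542 to 215138428, ERLIN1 on chromosome 10 from 100150094 to 100188334 and BECN1 on chromosome 17 from 42810134 to 42833350. The other named rises were ANK3 (2.06), a membrane adaptor protein, ITGA1 (1.99), a collagen-binding integrin subunit, OSTM1 (1.95), a lysosomal membrane protein, and SQLE (1.84), an enzyme of cholesterol synthesis. The other named falls were EML4 (-2.46), which binds microtubules, and NAA50 (-2.40), which acetylates protein N termini. In siSCR 1, ABCA12 stood at 65.5 against 28.8 to 32.0 in the other siSCR libraries, DEPDC1 at 58.8 against 204 to 216, and PRR11 at 463 against 1302 to 1439. Of the 8 named falls, 6 (ERLIN1, DEPDC1, EML4, NAA50, GCLM and BECN1) carried in the 3′ UTR a 7-mer of a family picked from these fold changes for lower levels in si1, as did 4 of the 8 named rises and 30.5% of uncalled genes. AKR1A1 carried none. In all, limma called 181 of 10517 genes at an adjusted p under 0.05, 83 higher and 98 lower in si1, and 2516 had an unadjusted p under 0.05. More were higher than lower with upper-quartile rescaling (110 and 95), voom (329 and 253), the mitochondrial covariate (15 and 13) and without siSCR 1 (725 and 674). The count was 1399 without siSCR 1 and 0 to 4 without any other library, where each named gene but BECN1, called without si1 2, lost its call. It was 5 with no filter, 28 with the mitochondrial share as a covariate and 1141 with all 11 libraries in one fit.

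With the preset correlation between genes, cell cycle genes were lower as sets with si1, and p53 targets and genes of cholesterol synthesis, lysosomes and ribosomal proteins were higher. With an estimated correlation, cholesterol synthesis and ribosomal proteins kept this (camera adjusted p = 0.0447), while S phase, mitosis, p53 and lysosome genes did not (camera adjusted p = 0.645 to 0.646). Among 35 splits of these libraries, the real one included, 10 gave as small a camera p for mitosis and 4 for S phase. For lysosomes 7 did, for p53 targets 3, for ribosomal proteins 2 and for cholesterol synthesis 1. Of 34 tested genes of DNA replication and S phase, 4 fell and 0 rose (20 fell adjusted over the list alone). Among them were the cyclin CCNE2 (-2.19, SE 0.40), the DNA polymerase subunit POLA2 (-1.94, SE 0.32) and the clamp loader subunit RFC3 (-1.88, SE 0.35). The list's median log2 fold change was -1.36 (camera adjusted p = 3.74e-11; adjusted p = 0.645 with an estimated correlation). Exons of CCNE2 and POLA2 share 37.0% and 35.1% of their bases with a neighbouring gene. None of the 32 mitosis genes passed the test on its own, over all genes or over the list alone, although all 32 had negative fold changes. The most abundant 2 were TOP2A (-1.67; limma adjusted p = 0.0903) and CENPF (-1.51; limma adjusted p = 0.166). The list's median was -1.53 (camera adjusted p = 3.46e-09; adjusted p = 0.646 with an estimated correlation). Of 26 p53 targets, BTG2 alone rose over all genes tested and 17 rose adjusted over the list alone (median 1.04; camera adjusted p = 4.21e-09; adjusted p = 0.645 with an estimated correlation).

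Within siSCR, replicate 1 stood apart in these same lists. Its S phase score was -0.48 against 0.79 to 0.84 in the other siSCR libraries, its mitosis score was -0.80 against 1.05 to 1.12 and its p53 score was 0.42 against -0.65 to -0.59. The si1 libraries had S phase scores of -1.24 to -0.53, mitosis scores of -1.90 to -0.29 and p53 scores of 0.61 to 0.75. Without siSCR 1, the medians for si1 were -1.64 for S phase, -2.03 for mitosis and 1.39 for p53 targets. With the mitochondrial share as a covariate they were -0.85, -0.75 and 0.68.

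**Figure D2:**
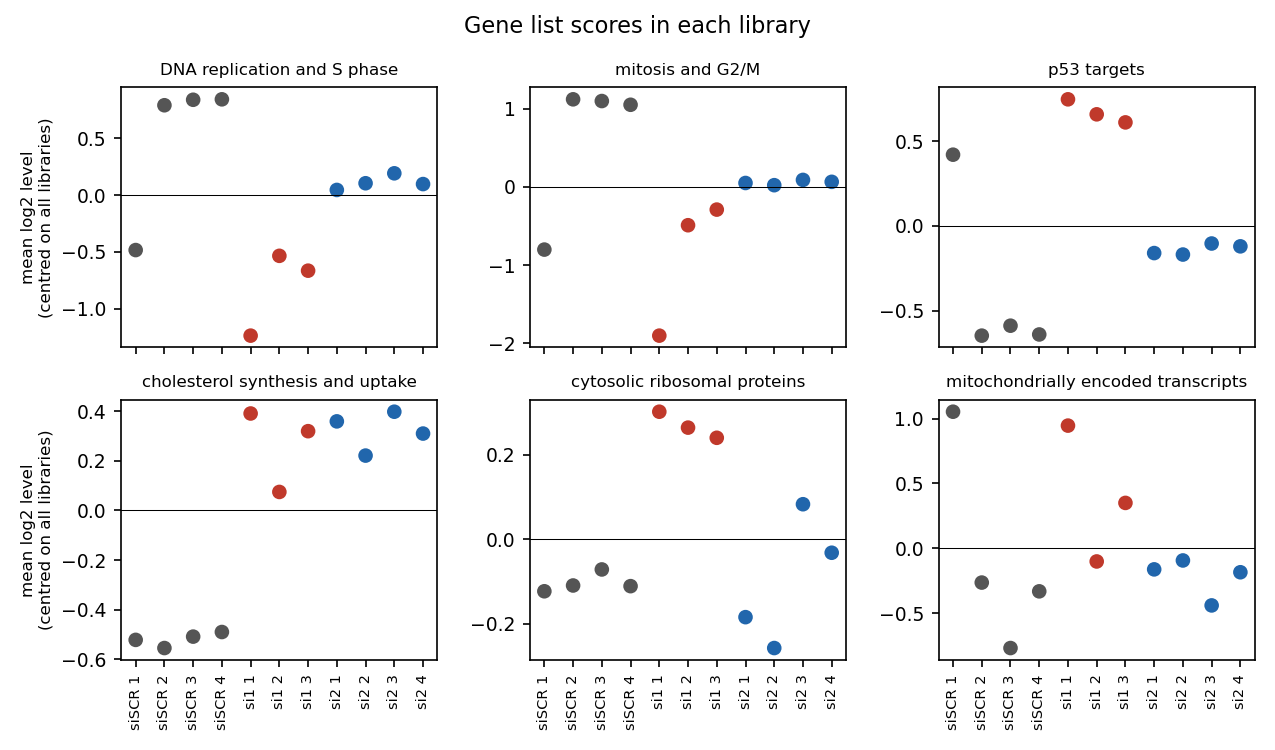
List scores (mean log2 level of the members, centred over all libraries; vertical axes) of 6 gene lists for each library, in grey for siSCR, red for si1 and blue for si2. In the S phase panel siSCR 1 lies at -0.48 and the other siSCR libraries at 0.79 to 0.84, while in the cholesterol panel all 4 siSCR libraries lie between -0.56 and -0.49.

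Of 23 tested genes of cholesterol synthesis and uptake, 6 rose and 0 fell with si1 (9 rose adjusted over the list alone), and 21 had positive fold changes. SQLE (1.84, SE 0.35), MSMO1 (1.82, SE 0.27), DHCR7 (1.70, SE 0.22) and INSIG1 (1.69, SE 0.21), which are sterol synthesis enzymes and a sterol-responsive regulator of the pathway, rose most. The median was 0.62 (camera adjusted p = 1.35e-06; adjusted p = 0.0447 with an estimated correlation). Ribosomal protein genes had a median of 0.39 over 34 members (camera adjusted p = 8.47e-08; adjusted p = 0.0447 with an estimated correlation), with 0 called over all genes and 3 rising adjusted over the list alone. RPLP1 and RPS14, the most abundant of them, had log2 fold changes of 0.61 and 0.24; such genes have near-identical copies elsewhere, which makes the assignment of reads uncertain. Lysosome and autophagy genes had a median of 0.43 with 0 of 22 called over all genes or the list alone, with CTSD at 0.47 and SQSTM1 at 0.55 (camera adjusted p = 0.00574; adjusted p = 0.646 with an estimated correlation). This list's camera adjusted p was 0.211 with the mitochondrial share as a covariate (median 0.18), and siSCR 1 had a lysosome score of 0.21 against -0.52 to -0.36 in the other siSCR libraries. In all, 6 of 30 lists passed with the preset correlation and 2 with an estimated one.

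Lists closest to the known chemistry of AKR1A1 did not pass the test with si1. None of 19 aldo-keto reductase and aldehyde genes was called (1 adjusted over the list alone; median 0.16, camera adjusted p = 0.273). Nor was any of 16 genes of glucuronate, inositol and polyol metabolism (2 adjusted over the list alone; median 0.25, camera adjusted p = 0.540). Of 25 NRF2 targets and glutathione genes, GCLM (-2.35), PIR (-1.76) and TKT (-1.37) fell and 0 rose (4 fell and 4 rose adjusted over the list alone; median 0.12, camera adjusted p = 0.918). ASS1, which makes argininosuccinate from citrulline, rose (1.70, SE 0.22) in the nitric oxide list of 10 genes (2 adjusted over the list alone; camera adjusted p = 0.473). LPCAT3, a lysophospholipid acyltransferase whose exons share 65.6% of their bases with EMG1, rose (1.38, SE 0.23) among 18 ferroptosis regulators (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.376). GPAM (-2.18), which starts glycerolipid synthesis, fell and LPIN1 (1.51), a phosphatidate phosphatase, rose among 19 genes of fatty acid synthesis and storage (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.191). No member was called, over all genes or the list alone, in fatty acid oxidation (camera adjusted p = 0.447), glycolysis (0.80), HIF targets (0.619), oxidative phosphorylation (0.273) or the tricarboxylic acid cycle (0.0514).

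The comparison of si2 with siSCR asks the same question for the second siRNA. TFRC, the transferrin receptor, rose from 155 ± 93.0 (n = 4) to 614 ± 203 (n = 4). KCNJ13, an inwardly rectifying potassium channel, rose from 39.4 ± 3.52 (n = 4) to 156 ± 23.7 (n = 4), and INSIG1, a regulator of cholesterol synthesis, from 89.7 ± 16.6 (n = 4) to 289 ± 51.1 (n = 4). MBNL1, a regulator of alternative splicing, fell from 446 ± 76.1 (n = 4) to 95.7 ± 17.3 (n = 4). UNG, which removes uracil from DNA, fell from 270 ± 48.5 (n = 4) to 77.6 ± 14.2 (n = 4). CD3EAP, a subunit of RNA polymerase I also named POLR1G, fell from 323 ± 80.3 (n = 4) to 89.2 ± 24.7 (n = 4). CRH, the corticotropin-releasing hormone, was at 7.56, 0, 0 and 1.02 in the siSCR libraries and at 44.6 to 221 in si2, so the size of its fold change depends on the pseudocount.

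The limma adjusted p was 0.00118 for KCNJ13 (log2 fold change 1.95, SE 0.17) and for MBNL1 (-2.21, SE 0.19), 0.00302 for UNG (-1.78, SE 0.20), 0.00363 for INSIG1 (1.68, SE 0.19), 0.00504 for CRH and 0.0203 for TFRC (2.10, SE 0.38). MBNL1 lies on chromosome 3 from 152243828 to 152465780, INSIG1 on chromosome 7 from 155297776 to 155310235 and HMGCS1 on chromosome 5 from 43289395 to 43313512. The other named rises were VCAM1 (1.80), an adhesion receptor for leukocytes, LPP (1.71), a focal adhesion protein, EPHA7 (1.65), an ephrin receptor, and HMGCS1 (1.63), an early enzyme of the mevalonate pathway. The other named falls were RPS19BP1 (-1.84), SH2B1 (-1.57), an adaptor of receptor kinases, CTPS1 (-1.49), which makes CTP, and SKP2 (-1.48), which marks cell cycle inhibitors for degradation. Exons of CD3EAP share 43.5% of their bases with ERCC1, those of KCNJ13 24.3% with GIGYF2 and those of HMGCS1 15.0% with an antisense transcript. In siSCR 1, VCAM1 stood at 42.0 against 20.9 to 24.4 in the other siSCR libraries and EPHA7 at 266 against 582 to 644. In si2 3, TFRC stood at 916 against 490 to 555 in the other si2 libraries. Of the 8 named falls, 5 (MBNL1, RPS19BP1, UNG, SH2B1 and CTPS1) carried in the 3′ UTR a 7-mer of a family picked from these fold changes for lower levels in si2, as did 3 of the 8 named rises and 21.1% of uncalled genes. Of the 8 named rises, 5 carried one of the control family, picked from these fold changes for higher levels in si2, as did 1 of the 8 named falls and 29.5% of uncalled genes. In all, limma called 320 of 10249 genes, 198 higher and 122 lower in si2, and 2008 had an unadjusted p under 0.05. The count was 1496 without siSCR 1 and 88 to 160 without any other library, and 11 of 22 named genes kept their call each time. It was 108 with no filter, 482 with limma-trend and 1159 with the mitochondrial share as a covariate. The named genes that lost the call without some library were SKP2, SQLE, TFRC, DUSP3, FNIP2, DCLK1, DHCR7, VCAM1, SH2B1, CTPS1 and EPHA7.

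Genes of cholesterol synthesis and uptake formed the list with the smallest p in si2: 11 of 23 rose and 0 fell (12 rose adjusted over the list alone). INSIG1 (1.68, SE 0.19), HMGCS1 (1.63, SE 0.20) and MSMO1 (1.54, SE 0.22) rose most. The median was 0.82 (camera adjusted p = 1.38e-11; adjusted p = 0.0180 with an estimated correlation). The list's score in siSCR 1 was -0.52, inside the range of the other siSCR libraries. In fatty acid synthesis and storage, SCD (1.21), LPIN1 (1.07) and ACLY (0.80) rose among 19 genes, and 6 rose and 1 fell adjusted over the list alone, while the list as a whole did not pass (median 0.32; camera adjusted p = 0.0519). SCD makes monounsaturated fatty acids and ACLY makes cytosolic acetyl-CoA.

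**Figure D3:**
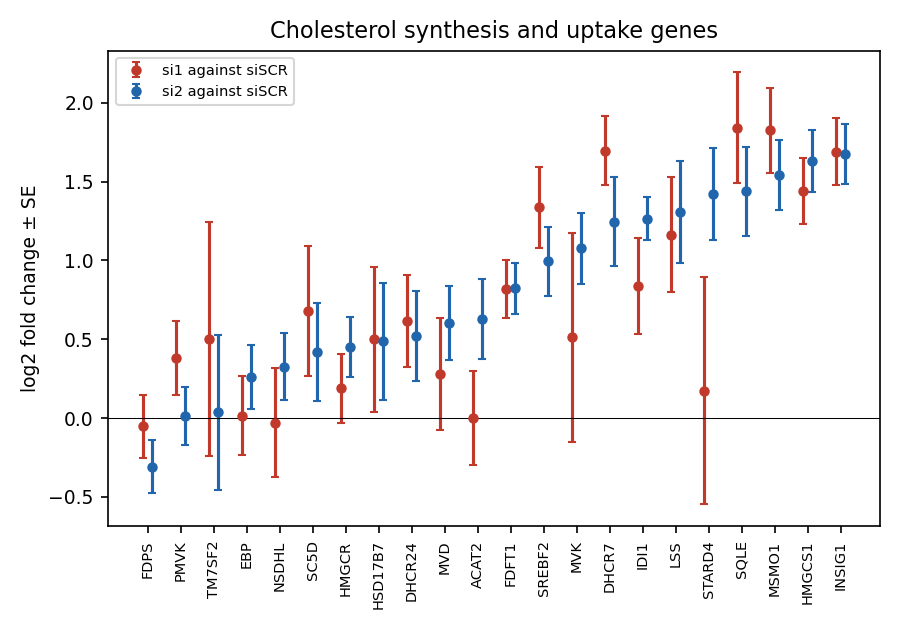
Log2 fold change against siSCR (vertical axis) of 22 of the 23 tested genes of cholesterol synthesis and uptake (horizontal axis), in red for si1 and blue for si2, with bars of 1 SE. INSIG1 lies at 1.69 in si1 and 1.68 in si2, and MSMO1 at 1.82 and 1.54.

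With the preset correlation, genes of S phase, mitosis, ribosome biogenesis and histones were lower in si2 as sets. With an estimated one none of the 4 passed (camera adjusted p = 0.423 to 0.644). Among 35 splits of these libraries, the real one included, 23 gave as small a camera p for S phase and 23 for mitosis. For ribosome biogenesis and for histones 4 did. S phase genes had a median of -0.42 with 0 of 34 called over all genes or the list alone (camera adjusted p = 0.000680; adjusted p = 0.644 with an estimated correlation). Mitosis genes had a median of -0.57 with 0 of 32 called either way (camera adjusted p = 0.000152; adjusted p = 0.644 with an estimated correlation). Of 26 MYC targets and ribosome biogenesis genes, SRM (-1.34, SE 0.23), the spermidine synthase, and WDR74 (-0.76, SE 0.17) fell and 0 rose (8 fell adjusted over the list alone; median -0.39, camera adjusted p = 0.000135; adjusted p = 0.597 with an estimated correlation). Replication-dependent histone genes had a median of -0.95 with 0 of 11 called over all genes and 9 falling adjusted over the list alone (camera adjusted p = 0.000135; adjusted p = 0.423 with an estimated correlation). They have near-identical copies, which makes the assignment of reads uncertain. The MYC list's score in siSCR 1 was -0.23 against 0.29 to 0.33 in the other siSCR libraries, and the S phase, mitosis and lysosome scores of siSCR 1 lay away from the other siSCR libraries as given above. Over left-out siSCR libraries, the median for si2 ran from -0.78 (without siSCR 1) to -0.27 (without siSCR 4) for S phase and from -1.08 (without siSCR 1) to -0.38 (without siSCR 2) for mitosis.

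Interferon-stimulated genes were higher in si2 as a set, with a median of 0.37, and 1 of 16 rose over all genes and over the list alone. The camera adjusted p was 0.00378 (adjusted p = 0.423 with an estimated correlation), and it was 0.182 with a minimum normalized count of 50 (median 0.13). Without siSCR 3 the median was 0.22, and 4 of 35 splits of the libraries, the real one included, gave as small a camera p. Lysosome and autophagy genes had a median of 0.38 with 0 of 22 called over all genes or the list alone (camera adjusted p = 0.00110; adjusted p = 0.597 with an estimated correlation). For lysosomes, 7 of 35 splits gave as small a camera p. In all, 7 of 30 lists passed with the preset correlation and 1, cholesterol synthesis, with an estimated one.

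Lists closest to AKR1A1 did not pass in si2 either. None of 19 aldo-keto reductase and aldehyde genes was called over all genes or the list alone (median 0.14, camera adjusted p = 0.509). Nor was any of 14 genes of glucuronate, inositol and polyol metabolism called over all genes (4 adjusted over the list alone; median 0.15, camera adjusted p = 0.221). Among 24 NRF2 targets and glutathione genes 0 were called over all genes (5 adjusted over the list alone; median 0.05, camera adjusted p = 0.910). Among 10 nitric oxide genes 0 were called (2 adjusted over the list alone; median 0.14, camera adjusted p = 0.422). Of 18 ferroptosis regulators, TFRC rose and ACSL4 (-0.89), which activates polyunsaturated fatty acids, fell, over all genes and over the list alone (camera adjusted p = 0.819). FAS, a death receptor, fell (-1.12, SE 0.17) among 26 p53 targets (2 rose and 1 fell adjusted over the list alone; median 0.27, camera adjusted p = 0.179). Ribosomal protein genes had a median of 0.01 with 0 of 34 called either way (camera adjusted p = 0.994). No member was called over all genes in fatty acid oxidation (camera adjusted p = 0.509), glycolysis (0.482), oxidative phosphorylation (0.509) or the tricarboxylic acid cycle (0.246), nor over the list alone. HIF targets had 0 calls over all genes and 2 adjusted over the list alone (camera adjusted p = 0.509).

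Genes called with both siRNAs were led by the sterol pathway: INSIG1 rose by 1.69 in si1 and 1.68 in si2, MSMO1 by 1.82 and 1.54, HMGCS1 by 1.44 and 1.63, SQLE by 1.84 and 1.44, and DHCR7 by 1.70 and 1.25. DCLK1 (1.46 and 1.24), a kinase that binds microtubules, FNIP2 (1.82 and 1.22), a partner of folliculin, and DUSP3 (1.60 and 1.15), a phosphatase, were the other named rises. AKR1A1 and MORC4 (-0.95 and -1.05), a chromatin ATPase, were the named falls. Over these 8 rises the limma adjusted p ranged from 0.0318 to 0.0491 in si1 and from 0.00363 to 0.0497 in si2, and for MORC4 it was 0.0425 and 0.0122. Of the 8 rises, 5 (HMGCS1, SQLE, DCLK1, FNIP2 and DUSP3) carried a 3′ UTR 7-mer of the control family, picked for higher levels in si2 than in siSCR. Of the families picked for lower levels, 4 carried one of the si1 family and 2 one of the si2 family. In all, 31 genes were called in the same direction with both, 28 higher and 3 lower, against 1.45 and 1.16 from independent lists of these sizes, and 3 were called in opposite directions. In 100 simulated data sets with shared controls and no siRNA effect, the highest such count was 0, which does not measure what shared controls add to an overlap of called genes. With 2 controls of its own for each siRNA, limma gave 0 shared genes in all 6 arrangements, in which si1 had 0 to 53 calls and si2 had 0 to 897. The count was 546 without siSCR 1, 0 or 1 without another siSCR library, 0 without any si1 library and 10 to 15 without any si2 library.

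Across 10187 genes tested in both comparisons, which are not independent replicates, fold changes of si1 and si2 had a Pearson r of 0.455 and a Spearman rho of 0.432. Simulated data with shared controls and no siRNA effect gave a mean r of 0.461 and a highest r of 0.490, so the correlation itself did not exceed what shared controls give. The covariance was 0.130 against a simulated mean of 0.0509 and a highest of 0.0561. With 2 controls of its own for each siRNA, r lay between 0.122 and 0.344 and the covariance between 0.0438 and 0.116.

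**Figure D4:**
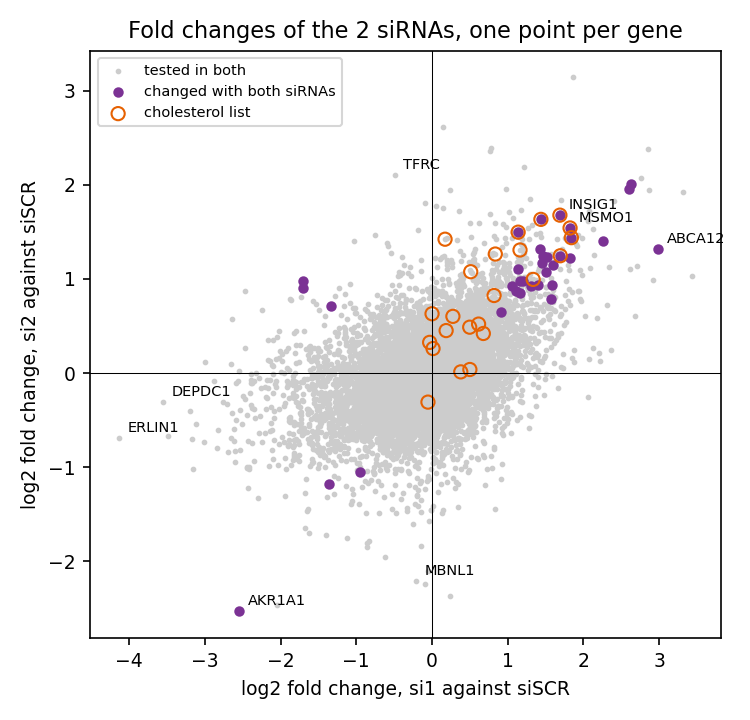
Log2 fold change of each gene in si1 (horizontal axis) and in si2 (vertical axis), both against siSCR, with genes tested in both in grey, genes called with both siRNAs in purple and the cholesterol list ringed in orange. AKR1A1 lies at -2.54 and -2.53, and MBNL1 (-2.21 in si2) lies near the vertical axis. ERLIN1 lies at -4.13 in si1, and its normalized counts were 50.4 to 68.3 in si2 against 57.9 to 128 in siSCR.

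The comparison of si2 with si1 sets the siRNAs, made against one gene, beside each other. EML4, which binds microtubules, was at 169 ± 40.6 (n = 4) in si2 and 25.9 ± 11.5 (n = 3) in si1, and DEPDC1 at 123 ± 8.11 (n = 4) and 14.5 ± 8.87 (n = 3). In the same order, COMMD8 was at 148 ± 13.6 (n = 4) and 24.1 ± 6.91 (n = 3), and TFRC at 614 ± 203 (n = 4) and 99.3 ± 22.7 (n = 3). FBXO32, a ubiquitin ligase component known from muscle atrophy, was at 68.5 ± 10.7 (n = 4) in si2 and 367 ± 55.5 (n = 3) in si1, and ANK3 at 20.1 ± 2.0 (n = 4) and 104 ± 14.6 (n = 3). MBNL1 was at 95.7 ± 17.3 (n = 4) and 383 ± 30.9 (n = 3), and ACSM3, a medium-chain acyl-CoA synthetase, at 30.3 ± 1.33 (n = 4) and 121 ± 32.2 (n = 3). The neighbours CRH and TRIM55 on chromosome 8, from 66176382 to 66178725 and from 66126896 to 66175487, differed in opposite directions, CRH higher in si2 (2.95, SE 0.50) and TRIM55 higher in si1 (-2.12, SE 0.41).

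The limma adjusted p was 0.00304 for COMMD8 (log2 difference, si2 minus si1, 2.60, SE 0.22), FBXO32 (-2.41, SE 0.20) and ANK3 (-2.31, SE 0.18), 0.00409 for MBNL1 (-2.0), 0.00541 for ACSM3 (-1.93), 0.00556 for TFRC (2.59), 0.00726 for EML4 (2.73) and 0.00967 for DEPDC1 (3.24). In all, limma called 704 of 10448 genes, 388 higher in si2 and 316 higher in si1, and 2654 had an unadjusted p under 0.05. The count was 419 without si1 3, 189, 142, 398 and 120 without si2 1, 2, 3 and 4, 230 with no filter, 1064 with limma-trend and 133 with the mitochondrial share as a covariate. CRH lost its call without si1 3 or si2 2, and TRIM55 lost it when any 1 of 4 libraries was left out. In si2 1, TRIM55 stood at 45.1 against 18.9 to 22.3 in the other si2 libraries.

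The siRNAs differed in p53 targets and, with the preset correlation alone, in cell cycle genes as sets, and did not differ detectably in cholesterol genes. Of 26 p53 targets, 7 were higher in si1 and 0 in si2 (19 and 1 adjusted over the list alone), with BTG2 (-1.93), SESN1 (-1.87), a stress-induced regulator of growth, FAS (-1.40) and the ribonucleotide reductase subunit RRM2B (-1.28) differing most. The median was -0.83 (camera adjusted p = 4.31e-10; adjusted p = 0.0308 with an estimated correlation). Of 34 S phase genes, 12 were higher in si2 and 0 in si1 (20 higher adjusted over the list alone), among them GINS3 (1.97), CCNE2 (1.93), UHRF1 (1.86) and POLA2 (1.62). The median was 0.88 (camera adjusted p = 5.90e-10; adjusted p = 0.499 with an estimated correlation). Of 32 mitosis genes, BUB1B (1.28), a spindle checkpoint kinase, was higher in si2 (11 higher adjusted over the list alone; median 0.98, camera adjusted p = 3.84e-08; adjusted p = 0.802 with an estimated correlation). Ribosomal protein genes had a median of -0.42 with 0 of 34 called either way (camera adjusted p = 2.34e-06; adjusted p = 0.677 with an estimated correlation). Of 13 mitochondrially encoded transcripts, MT-CO3 (-1.35) and MT-ATP6 (-1.16) were higher in si1 (4 adjusted over the list alone; median -0.58, camera adjusted p = 0.00104; adjusted p = 0.802 with an estimated correlation), and the list did not pass without si1 1 (adjusted p = 0.10). The median of the mitosis list was 0.52 without si1 1 and that of the mitochondrial list -0.32. With the mitochondrial share as a covariate, the p53 list had a median of -0.50 (adjusted p = 0.00460) and the S phase list did not pass (median 0.42; adjusted p = 0.826). The mitosis list then turned direction (median -0.41; adjusted p = 0.0192) and the mitochondrial list did not pass (median 0.50; adjusted p = 0.298). Of 3 tested fibroblast markers, too few for a list test, COL1A1 (1.38) and S100A4 (1.15) were higher in si2. Cholesterol genes had a median of 0.00 with 0 of 24 called over all genes or the list alone, and fold differences from -0.46 to 1.25 (camera adjusted p = 0.977). In all, 5 of 30 lists passed with the preset correlation and 1, p53 targets, with an estimated one.

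The authors' deposited table gave 1050 genes at an adjusted p under 0.05 for si1, 485 higher and 565 lower, and 617 for si2, 373 higher and 244 lower. Of the limma calls, 171 and 290 were among them. The authors' log2 fold changes had a Pearson r of 0.955 and 0.961 with those of limma across genes. For AKR1A1 the authors' deposited table gave log2 fold changes of -2.06 (adjusted p = 2.89e-08) for si1 and -2.20 (adjusted p = 1.36e-20) for si2.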

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

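The AKR1A1 level of siSCR 1 as a test of its label, the correlation of siSCR 1 with si1 1, the cholesterol list without siSCR 1, the count without si1 2 and the 7-mer scores and odds ratios were tests chosen after the result was seen. Libraries were looked at for values far from the rest of their group in 110 groups of 4, by the gap to the nearest library over the range, beyond Dixon's 95% bound. Chance marks about 1 in 20 groups; 18 were marked, 14 of them for siSCR 1, and lists and genes that move together do not count as separate groups.

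The siRNAs differed in many genes by limma tests of si2 against si1, and in 5 lists by camera with the preset correlation, of which p53 targets alone passed with an estimated one. The log2 difference was 3.24 for DEPDC1, 2.95 for CRH, 2.73 for EML4, 2.60 for COMMD8, 2.59 for TFRC, -2.41 for FBXO32, -2.31 for ANK3, -2.12 for TRIM55, -2.0 for MBNL1 and -1.93 for ACSM3. List medians were 0.88 for S phase (adjusted p = 0.499 with an estimated correlation), 0.98 for mitosis (0.802), -0.83 for p53 targets (0.0308), -0.42 for ribosomal proteins (0.677) and -0.58 for mitochondrial transcripts (0.802). With the mitochondrial share as a covariate the mitosis median turned to -0.41 and the mitochondrial one to 0.50, and S phase did not pass (adjusted p = 0.826).

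For these differences, 1 of 35 splits of the libraries gave as many genes as the real 704, and the highest other split gave 0. This argues against chance but cannot exclude it, since 1 of 35 is the smallest share that the splits allow. The low number of genes detected in si1 2 was argued against by the 803 genes that differed without it. Unequal loss of AKR1A1 cannot be told apart: over 647 differing genes r between the siRNAs' fold changes was 0.0435, with 410 of opposite sign, which lay between the bounds of 0 and 0.5 set for that test, and the interval of the AKR1A1 difference ran from -0.89 to 0.92. A candidate explanation is that each siRNA lowers transcripts with sites for its own 5′ end: with trends in 3′ UTR length, GC content and level removed, TGAGATA of si1 scored 11.2 and CAGTTAC of si2 scored -7.09, beyond the 5.58 and -5.21 reached in 1000 permutations, and GAATATA of the control scored -0.79. Odds ratios against uncalled genes, without that correction, were 3.99 for si1 7-mers in genes higher in si2 and 2.01 for si2 7-mers in genes higher in si1. For control 7-mers in genes higher in si2 the odds ratio was 1.77. The 7-mers were picked from fold changes of these same libraries, so the odds ratios describe the genes and are no test. No biological explanation was tested.

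Cholesterol genes rose with both siRNAs, and 1 of 35 splits gave as small a camera p in each comparison. That p was 2.25e-07 in si1, with 3.58e-07 the lowest of the other splits, and 4.60e-13 in si2, with 2.89e-09. As 1 of 35 is the smallest share that the splits allow and 30 lists were tested, chance cannot be excluded. The fatty acid synthesis list, which did not pass, also had 1 of 35 in each comparison, and both comparisons share their controls. siSCR 1 as the cause was argued against by an adjusted p of at most 8.93e-05 without it, and GC content, transcript length and level by at most 1.11e-06 after their trend was removed. Sites for the control siRNA cannot be told apart. Without the members that carry a control 7-mer or whose 3′ UTR was not searched, 18 of 23 stayed, with a camera adjusted p of at most 8.80e-05. Their medians were 0.56 in si1 and 0.62 in si2, against 0.62 and 0.82. The 4 members that carry one had medians of 0.81 and 1.43, but the 7-mers were picked for higher levels in si2, so this is no test. Over all searched genes, those with a control 7-mer had medians of 0.040 in si1 and 0.085 in si2, against -0.062 and -0.043 without. Whether such sites account for part of the rise was left open. Lower AKR1A1 stays open as the biological explanation that the design names.

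The library siSCR 1 stood apart from the other siSCR libraries. Its 10 most abundant genes took 12.2% of the reads against 5.33% to 5.63%, and its mitochondrial share was 12.1% against 3.46% to 4.46%. Its list scores were -0.48 for S phase, -0.80 for mitosis, 0.42 for p53 targets and -0.23 for MYC targets. Single genes far from the other siSCR libraries were ABCA12 at 65.5, DEPDC1 at 58.8, PRR11 at 463, CRH at 7.56, VCAM1 at 42.0, EPHA7 at 266, FBXO32 at 146 (against 14.4 to 24.6) and ACSM3 at 57.1 (against 6.41 to 13.2).

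A wrong label on a knockdown library was argued against by its AKR1A1 count of 390, the highest of all 11 libraries. GC content, transcript length and level accounted for a share of 0.0493 of the variance of its deviations, too little to be the cause. A batch shared with si1 1 is a candidate explanation: the deviations of siSCR 1 and si1 1 from their groups correlated at 0.402 across genes, the best of the 12 pairs, with 0.147 the next highest, and both had high mitochondrial shares. The labels give no batch, and a difference in the growth state of the cells was not tested. With si1, 2 of 35 splits gave at least as many genes as the real 181, and the other, siSCR 2 to 4 against the rest, gave 1065, so chance cannot be excluded and this large count points to a structure of the samples.

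For si2, 1 of 35 splits gave as many genes as the real 320, with 0 the highest other. This argues against chance but cannot exclude it, since 1 of 35 is the smallest share that the splits allow. For the number of lists past the threshold chance cannot be excluded either: 17 of 35 splits gave at least the real 6 in si1. In si2, 13 of 35 gave at least the real 7, with 10 the highest other in each.

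KCNJ13 stood at 34.2 in siSCR 2 against 40.6 to 41.8 in the other siSCR libraries. NAA50 stood at 217 in si2 3 against 155 to 160.1 in the other si2 libraries. TFRC stood at 916 in si2 3 against 490 to 555. TRIM55 stood at 45.1 in si2 1 against 18.9 to 22.3.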

How the results depend on the processing

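The voom fit, the mitochondrial covariate and the fits without both siSCR 1 and si1 1 were chosen after seeing the data, as were some settings for AKR1A1, the lists and the correlation; the rest were planned. The count-based test planned for raw counts, edgeR, was not run, since the deposited unit was log2. Upper-quartile rescaling took the place of another normalization. Counts are given for si1, si2, si2 against si1 and both siRNAs, where they moved by over 1.5 times from 181, 320, 704 and 31. With no filter, which adds weakly expressed genes to the adjustment, they were 5, 108, 230 and 0. A minimum of 50 gave 567 for si1 and 94 for both, limma-trend gave 712, 482, 1064 and 110, and voom gave 582 for si1, 1172 for si2 against si1 and 100 for both. All 11 libraries in one fit gave 1141 for si1 and 116 for both, and a pseudocount of 5 gave 414 and 73. The mitochondrial covariate gave 28, 1159, 133 and 12, with an r between fold changes of 0.335. Without both siSCR 1 and si1 1 the counts were 864 for si1, 1496 for si2 and 385 for both. A log2 fold change of at least 1 in size left 169 for si2 and 20 for both, by its construction. With an estimated correlation 2 lists passed in si1 and 1 in si2. The estimate was -0.00202 for cholesterol in si1 and 0.00902 for p53 targets in si2 against si1, both below the preset. Yet their camera adjusted p rose from 1.35e-06 to 0.0447 and from 4.31e-10 to 0.0308. A larger correlation therefore cannot account for the rise in these lists. Apart from the limit on fold change and the filter, the cause was not tested.

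The replicate numbers missed the rule set for pairing, under which each r of deviations between samples of 1 number had to exceed 0.1. For siSCR, r was 0.402, 0.0930 and 0.147 with si1, and 0.102, -0.0325, 0.176 and 0.0882 with si2. For si1 with si2 it was 0.110, -0.00697 and 0.0399. Yet the highest r of each comparison came from a pair with the same number, so a structure shared by replicate numbers cannot be excluded. As a block the replicate numbers gave 0 (2051 with an unadjusted p under 0.05 by limma), 175, 6 and 0 genes. AKR1A1 in si1 was then at -2.59 (limma adjusted p = 0.147). These fits used only numbers present in both groups, so siSCR 4 was left out for si1 and si2 4 for si2 against si1. Leaving out these libraries without a block gave 0 and 120 genes. The count of 0 for si1 and the adjusted p of AKR1A1 in si1 therefore cannot be assigned to the block itself. With split controls r was 0.322, 0.344, 0.322, 0.122, 0.177 and 0.163.

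Leaving out 1 library in turn gave 0 to 1399 genes for si1 (1693 to 3404 with an unadjusted p under 0.05 by limma), 88 to 1496 for si2, 120 to 803 for si2 against si1 and 0 to 546 for both, each highest but the third without siSCR 1, the third without si1 2. It gave 6 to 9 lists for si1, 7 to 9 for si2, an r of 0.384 to 0.611, and AKR1A1 at -2.98 to -2.10 in si1 and -2.66 to -2.34 in si2. AKR1A1 in si1 kept its direction throughout, with an adjusted p of 0.0659 to 0.126 without any library but siSCR 1, and 0.0871 with no filter (-2.54). Without siSCR 1 the lowest correlation within siSCR was 0.970 in place of 0.916. Correlations were taken as moved beyond 0.1, and those within groups beyond 0.02. Of 1011 results of named genes under these settings 711 kept direction and call, 300 lost the call and 0 reversed.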

Other observations

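Stress and signalling genes showed scattered changes. With si1, OAS3, an interferon-induced sensor of double-stranded RNA, fell (-2.38, SE 0.42) among 14 interferon-stimulated genes (1 adjusted over the list alone; median 0.25, camera adjusted p = 0.516). PMAIP1 rose among 20 apoptosis regulators (1 adjusted over the list alone; median -0.19, camera adjusted p = 0.777). With si2, VCAM1 (1.80) and TNFAIP3 (1.21), an inhibitor of NF-kB signalling, rose among 9 NF-kB targets (3 adjusted over the list alone; median 0.14, camera adjusted p = 0.109). COL4A1 (1.14), a basement membrane collagen, rose among 24 TGF-beta response and matrix genes (5 rose and 1 fell adjusted over the list alone; median 0.19, camera adjusted p = 0.0784), and PRKRA (0.65), a partner of Dicer, rose among 14 small RNA pathway genes (1 adjusted over the list alone; median 0.04, camera adjusted p = 0.982). MAL2 (1.23), an apical sorting protein, rose in si1 among 12 epithelial junction genes (2 rose and 2 fell adjusted over the list alone; median -0.03, camera adjusted p = 0.883). Heat shock genes in si1 had a median of -0.46 (camera adjusted p = 0.0514), with 0 of 16 called over all genes, 2 rising and 2 falling adjusted over the list alone, and HSP90AA1 at -1.14 (limma adjusted p = 0.0512).

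Between the siRNAs, several oxidative stress and metabolic genes differed one by one while their lists did not pass. GCLM (2.27), PIR (1.88), SLC7A11 (1.46), the cystine transporter, and TKT (1.33) were higher in si2 among NRF2 targets, 1 of which was higher in si1 (camera adjusted p = 0.888). ALDH1A1 (-1.50) and AKR1C1 (-1.16) were higher in si1 among aldo-keto reductase and aldehyde genes (camera adjusted p = 0.484), and SLC2A13 (-1.47), an inositol transporter, and MIOX (-1.10), which opens the inositol ring, in the polyol list (camera adjusted p = 0.977). Among ferroptosis regulators, ACSL4 (-1.41) and FTL (-0.82) were higher in si1 and TFRC and SLC7A11 in si2 (camera adjusted p = 0.570). In the fatty acid synthesis list, GPAM (2.10), SCD (1.10) and ACSL3 (0.88) were higher in si2 (camera adjusted p = 0.977), as were USP18 (2.42) and OAS3 (2.37) among interferon-stimulated genes (camera adjusted p = 0.197). So were AQP1 (2.21), a water channel of the proximal tubule, and VCAM1 (1.90) in the renal list (camera adjusted p = 0.681). CLDN1 (1.51) was higher in si2 in the epithelial list, where MAL2 (-1.05) was higher in si1 (camera adjusted p = 0.484).

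Lists with no called member in si1 were the ATF4 response (6 adjusted over the list alone; camera adjusted p = 0.481), endoplasmic reticulum chaperones (0; 0.734), NF-kB targets (1; 0.619), TGF-beta response and matrix (4; 0.80), renal lineage (2; 0.432), MYC targets (0; 0.376), histones (3; 0.123), mitochondrial transcripts (0; 0.135) and the small RNA pathway (3; 0.896). In si2 they were the ATF4 response (2 adjusted over the list alone; camera adjusted p = 0.509), endoplasmic reticulum chaperones (0; 0.221), heat shock (0; 0.246), epithelial junctions (0; 0.291), apoptosis (0; 0.509) and mitochondrial transcripts (0; 0.509), and the renal list had VCAM1 as its 1 call (2 adjusted over the list alone; 0.422). For the ATF4 and NF-kB lists in si1 and the small RNA list in both, the sign of the median and the direction of camera differed. Of fibroblast markers COL1A1 and S100A4 were tested in both comparisons with siSCR, of leukocyte markers CD68, and of endothelial markers none, too few for a list test. COL1A1 was at -0.66 in si1 and 0.72 in si2 (limma adjusted p = 0.350 and 0.232), and both fibroblast markers rose in si2 adjusted over the list alone. In si2 against si1, COL1A1 (1.38) and S100A4 (1.15) were called higher in si2 of 3 fibroblast markers tested.

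The 7-mer search and all of its tests were chosen after the result was seen, and the 7-mers and their families were picked from the same fold changes. Each permutation therefore took the most extreme score of all 7-mers. The 3′ UTRs of 9794 genes in si1 and 9598 in si2 were searched, and genes are not independent. In si1 the lowest score was -10.8, for TGAGATA, with -5.35 the lowest in 1000 permutations (permutation p = 0.001, the smallest they can give). In si2 this 7-mer scored -0.52. In si2 the lowest was -10.6, for CAGTTAC, with -5.15 the lowest in permutations (permutation p = 0.001, the smallest they can give). In si1 it scored -0.20. Among genes that fell in si1, 67 of 92 carried a 7-mer of the first family, 72.8% against 30.5% of uncalled genes. Among those that fell in si2, 64 of 115 carried one of the second, 55.7% against 21.1%. These shares follow in part from how the families were picked and are not corrected for 3′ UTR length, so they describe the genes and are no test. From the scores, matches between an siRNA's 5′ end and 3′ UTRs may have lowered part of the genes that carry them. The siRNA sequences were not given in the sources used here, so this is a hypothesis.

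GAATATA had the highest score in both comparisons with siSCR, 7.98 in si1 and 11.0 in si2, and -0.79 in si2 against si1. Of genes that rose, 41 of 74 in si1 and 122 of 192 in si2 carried a 7-mer of its family, with the same limits. Genes with such sites may have been lower in siSCR through the control siRNA, which would make them higher with both siRNAs. Without siSCR 1 the scores were 8.25 and 10.8, and those of TGAGATA and CAGTTAC -9.57 and -8.21. With either strand counted, the lowest-scoring 7-mer of each siRNA, 2 of 2, lay in an AKR1A1 transcript. TGAGATA lay in 1 of 14 on the same strand. CAGTTAC lay in 0 of 14 on the same strand and in 5 of 14 on the other strand. CTGAGAT, which overlaps TGAGATA and scored -9.89 in si1, lay in 9 of 14 on the same strand. AGTTACA, which overlaps CAGTTAC and scored -9.84 in si2, lay in 0 of 14 on either strand, as did GAGATAC of the si1 family. On the other strand, TTGAGAT of the si1 family lay in 1 and AGTTACT of the si2 family in 2. Of all 7-mers, 16.4% lie there on the same strand and 28.6% on either. As overlapping 7-mers are not independent and the strand differed between the siRNAs, whether these matches exceed chance was left open.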
